A study of Mus musculus with 6 samples.

How the data were processed

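RNA was measured in whole colon tissue of BALB/c mice in 6 libraries, 3 of mice given 5-fluorouracil and 3 of mice given 5-fluorouracil and berberine, grouped by the labels. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected with oligo(dT), and strand-marked libraries with molecular identifiers in the adapters were sequenced as paired reads of 150 bases on a NovaSeq. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2, edgeR and the mouse build GRCm38, with no role or order. The annotation version is not given in the sources used here, nor is whether the molecular identifiers were used in counting.

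The deposited table holds, for each library, estimated counts as whole numbers and FPKM (fragments scaled to transcript length and library depth), both computed by the authors. For at least 98.1% of the genes with 1 transcript and over 50 counts, the deposited count was within 2% of the FPKM times the transcript length and a constant of the library. The counts are thus estimates from coverage, and 1 fragment can be worth about 4 counts, which makes low counts look more precise than they are. A floor of 3 fragments, taken as 12 counts over a group, was used for bounds against groups with 0 counts; these bounds cover counting error only. Gene symbols and coordinates are those of the deposited table. H2-Q, immunoglobulin, haemoglobin, Gsta, Mcpt and Saa genes belong to families of similar copies, and their single values are uncertain because reads can be split between copies.

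The counts were used as deposited. Their sum was 55542521, 63831168 and 53970545 in the 5-Fu libraries 1 to 3 and 61820101, 54067678 and 53824752 in the 5-Fu+BBR libraries 1 to 3. Genes were filtered with filterByExpr, which left 20101 of 30777, scaled with TMM and tested with edgeR 4.0.16's robust quasi-likelihood test in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and no covariates. The biological coefficient of variation was 0.296. CPM are counts scaled to the TMM-adjusted library size. Chi-square values per gene between libraries ranged from 23.7 to 63.9, so no pair of libraries agreed within sampling noise. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 for lists with at least 4 members tested, with adjustment over the lists, and again with an estimated correlation and with fry, for a common direction and, read after the other results, for either direction. Counts adjusted over the list alone apply Benjamini-Hochberg adjustment within a list. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

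The groups, the test, 50 gene lists, 22 key genes, the rule for named genes and most alternatives were set before the data were examined. The rule named up to 10 genes per direction that passed, did not overlap between groups and had a mean FPKM of at least 1, filled up with genes of the smallest p, and left out predicted genes and receptor segments; it also named the key genes and up to 4 members with the smallest p from each list that passed or had a member that passed. Other members were named because they passed when adjusted over the list alone, that is, after their values were seen. Kidney genes were looked at because some, such as Kap and Umod, had been seen to be high; others, such as Slc34a1 and Nphs1, were then written down before their values were seen.

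The steps were tested on simulated data, after the first fit to the real data. In 5 simulations of this comparison over 19560 genes, 45.8% of genes changed 2-fold and 85.4% of genes changed 4-fold were found. There were 200 such genes per simulation, drawn from genes with a mean of at least 1 CPM, so these shares do not cover lower genes. The simulated counts also left out that 1 fragment can be worth about 4 counts. Unchanged genes made up 11 to 13 of the 139 to 149 calls per simulation, 8.34% on average and above the 5% that the threshold allows for. A list of 25 genes shifted 1.5-fold was found in 5 of 5 simulations and 0 of 195 unchanged lists were called, although simulated genes vary independently, unlike real ones. The alternatives were a replicate block, no filter, a filter of 50 counts in 3 samples, DESeq2 size factors, limma-voom with and without sample weights, DESeq2 1.42.0, an adjusted p of 0.1 and leaving out each library. Chosen after seeing the data were counts divided by 4, edgeR's newer quasi-likelihood method, limma-trend on log2(FPKM + 1) for genes with an FPKM of at least 1 in 3 samples, and 5-Fu+BBR replicate 1 alone against 5-Fu.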

Results

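Gene expression was measured by RNA sequencing of colon tissue from BALB/c mice, a common inbred laboratory strain. Of the 6 libraries, 3 came from mice given 5-fluorouracil (5-Fu), a pyrimidine analogue used in chemotherapy that damages the dividing cells of the intestinal lining. The other 3 came from mice given 5-fluorouracil together with berberine, a plant alkaloid (5-Fu+BBR). The deposited estimated counts summed to between 53824752 and 63831168 per library over 30777 genes. Of these, 20101 genes were expressed highly enough to be tested. The labels do not say whether the 3 samples of a group came from separate animals, so the p-values measure only the spread between these samples. Levels are given as CPM, counts scaled to the size of the library, as the mean ± SD of 3 libraries per group (n = 3), and log2 fold changes, 5-Fu+BBR minus 5-Fu, are given ± SE.

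The only comparison of the design asked which genes in the colon differ when berberine is added to 5-fluorouracil. At an adjusted p under 0.05 by edgeR's quasi-likelihood test, 12 genes were higher and 3 were lower in 5-Fu+BBR. In each case the 3 libraries of one group all lay above those of the other. The genes that rose included the antigen presentation genes Cd74, H2-Ab1, H2-Q5 and H2-Q7, the clock genes Dbp and Nr1d1, and C1qtnf3, Enpp2 and Cav1. The genes that fell were Sgk1, E2f2 and Pgap1. At an unadjusted p under 0.05, 3128 genes differed, 1905 higher and 1223 lower, where chance alone would give 1005 on average. With a change of at least 2-fold as well, 952 were higher and 179 lower. Genes vary together, so counts can lie far from that average. Other splits of the 6 samples into 3 and 3 gave between 163 and 1549 genes at an unadjusted p under 0.05 by edgeR. The groups did not overlap for 2466 genes that were higher and 1946 that were lower. These were 21.9% of the genes tested, where chance gives 10% on average.

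Cd74 encodes the invariant chain that accompanies MHC class II molecules through the cell (ENSMUSG00000024610, chromosome 18, 60803848 to 60812646 of GRCm38). It was present at 321 ± 38 CPM in 5-Fu and 1027 ± 119 CPM in 5-Fu+BBR, 3.2-fold higher (log2 fold change 1.68 ± 0.15, adjusted p = 0.0161). H2-Ab1, a class II beta chain (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), rose from 53.1 ± 9.05 to 170.0 ± 22.9 CPM (log2 fold change 1.68 ± 0.16, adjusted p = 0.0178). The class I genes H2-Q5 (ENSMUSG00000055413, chromosome 17, 35394126 to 35397588) and H2-Q7 (ENSMUSG00000060550, chromosome 17, 35439155 to 35443773) rose by 1.62 ± 0.14 and 1.45 ± 0.12 on the log2 scale, with an adjusted p of 0.0161 for both. H2-Q6, next to them, was at 70.2 ± 1.61 against 166 ± 36 CPM and did not pass (adjusted p = 0.0517). H2-Q5 is annotated as a polymorphic pseudogene. H2-Q genes are near-identical copies among which the authors' counting could split reads. The reads are from BALB/c while GRCm38 represents C57BL/6J, so the values of single H2 genes are uncertain.

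Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203) encodes a transcription factor driven by the circadian clock. Its level was 20.2 ± 1.99 CPM in 5-Fu and 56.5 ± 9.92 CPM in 5-Fu+BBR (log2 fold change 1.48 ± 0.15, adjusted p = 0.0228). Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333), the clock repressor also called REV-ERBα, was at 49.9 ± 11.3 against 133 ± 16.8 CPM (log2 fold change 1.42 ± 0.17, adjusted p = 0.0495). C1qtnf3 (ENSMUSG00000058914, chromosome 15, 10952332 to 10980150), which encodes a secreted C1q/TNF-related protein, had the largest change among the named genes that passed, from 1.98 ± 0.272 to 13.1 ± 2.76 CPM (6.62-fold, log2 fold change 2.73 ± 0.24, adjusted p = 0.0161). Enpp2 (ENSMUSG00000022425, chromosome 15, 54838901 to 54920125), which encodes the lysophosphatidic acid-producing enzyme autotaxin, rose 2.01-fold (log2 fold change 1.0 ± 0.10, adjusted p = 0.0178). Cav1 (ENSMUSG00000007655, chromosome 6, 17306335 to 17341324), the main structural protein of caveolae, rose 1.88-fold (log2 fold change 0.91 ± 0.11, adjusted p = 0.0435). The other 3 genes that rose were 2 immunoglobulin variable segments and 1 predicted gene, annotated as an unprocessed pseudogene. The predicted gene had 0 counts in 5-Fu and was at least 22.5-fold higher in 5-Fu+BBR (Gm6951, named after its values were seen).

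Sgk1 (ENSMUSG00000019970, chromosome 10, 21882184 to 21999893), a kinase induced by corticosteroids that promotes sodium uptake in the colon, fell 2.75-fold, from 159.8 ± 32.3 to 58.1 ± 3.33 CPM (log2 fold change -1.46 ± 0.15, adjusted p = 0.0228). E2f2 (ENSMUSG00000018983, chromosome 4, 136172394 to 136196057), a transcription factor of the cell cycle, fell 2.07-fold, from 60.9 ± 7.04 to 29.4 ± 1.38 CPM (log2 fold change -1.05 ± 0.12, adjusted p = 0.0318). Pgap1 (ENSMUSG00000073678, chromosome 1, 54472994 to 54557684), an enzyme that remodels GPI anchors, fell 1.82-fold (log2 fold change -0.86 ± 0.10, adjusted p = 0.0363). The genes with the next smallest p among those lower in 5-Fu+BBR did not pass. They were Fam102b, Gda, Otud6b, Prom1, Smad4, Nipal1 and Mmgt1, with log2 fold changes of -0.91, -1.6, -0.67, -1.44, -0.73, -0.89 and -0.60 and adjusted p values between 0.0566 and 0.091.

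**Figure D1:**
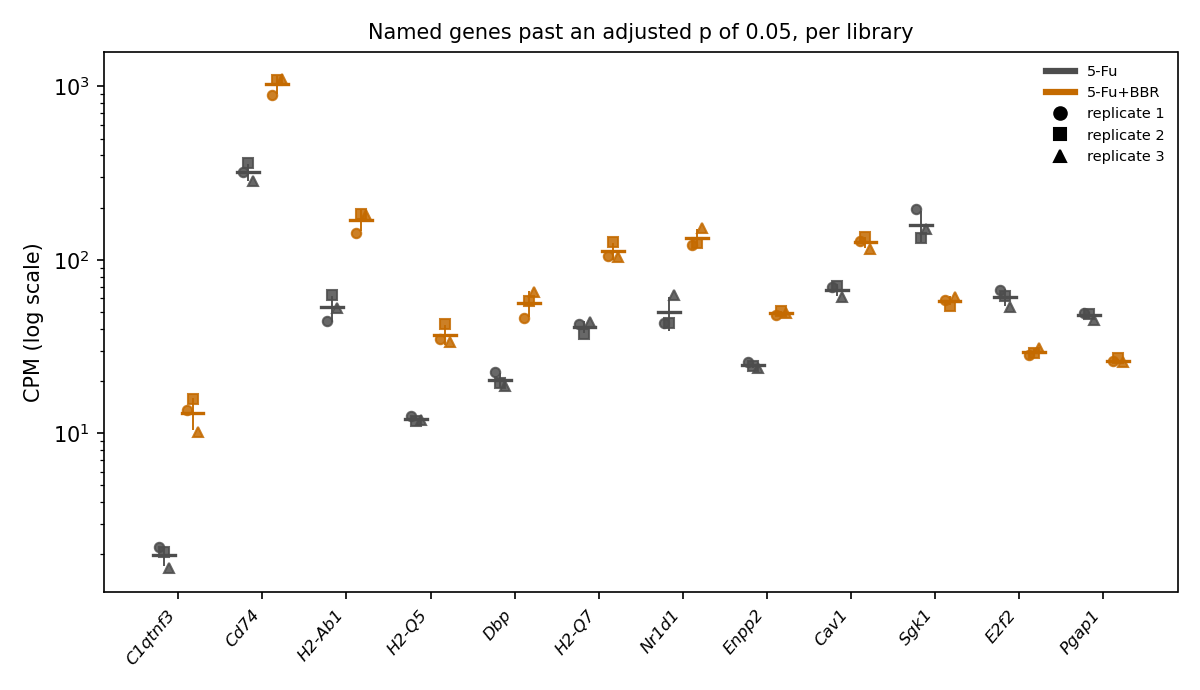
CPM (log axis) of the 12 named genes that passed an adjusted p of 0.05, with 1 point per library, a bar at the mean of the 3 libraries of each group and a line over 1 SD. Cd74 lay between 283 and 359 CPM in 5-Fu and between 891 and 1109 CPM in 5-Fu+BBR, and Sgk1 lay between 134 and 196 CPM in 5-Fu and between 54.5 and 61 CPM in 5-Fu+BBR.

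Transcripts of kidney genes, looked at because some had been seen to be high, were high in 2 of the 3 libraries of 5-Fu+BBR. Kap, an androgen-regulated gene of the kidney proximal tubule, was at 7.89, 7.92 and 10.5 CPM in 5-Fu replicates 1 to 3 and at 10, 109 and 105 CPM in 5-Fu+BBR replicates 1 to 3. Umod, which encodes uromodulin of the loop of Henle, was at 0.811, 0.953, 1.08, 1.32, 14.6 and 12.5 CPM in the same order. Slc34a1, a phosphate transporter of the proximal tubule, was at 6.89 ± 0.621 against 20.7 ± 12.5 CPM (log2 fold change 1.59 ± 0.53, adjusted p = 0.245). Nphs1 and Gatm, also kidney genes, were at 34.6 ± 6.13 against 24.3 ± 5.84 CPM and 26.2 ± 1.73 against 24.9 ± 3.37 CPM, levels that 5-Fu libraries reached as well. The same 2 libraries had the lowest medians of neutrophil and antimicrobial defence genes and the highest of mast cell, adipocyte, T and NK cell, B and plasma cell, dendritic cell and smooth muscle genes. The 15 genes that passed include 0 of the kidney genes examined. Genes high in only 2 of the 3 libraries vary widely within 5-Fu+BBR and so hardly pass. Kap, for example, was 8.52-fold higher with an adjusted p of 0.209 by edgeR. The 0 therefore does not show that the genes that passed are free of kidney RNA.

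**Figure D2:**
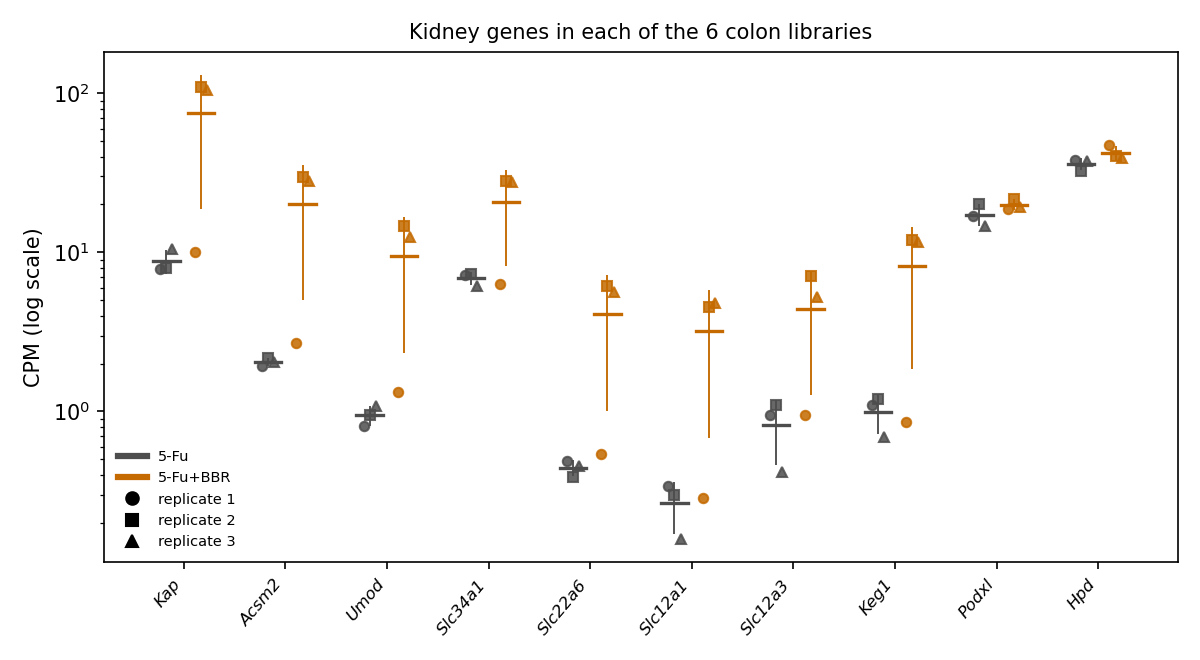
CPM (log axis) of 10 kidney genes in each library, with 1 point per library, a bar at the mean of each group and a line over 1 SD. For Kap, Acsm2, Umod, Slc34a1, Slc22a6, Slc12a1, Slc12a3 and Keg1, 5-Fu+BBR replicates 2 and 3 lay above the other 4 libraries, while the 6 libraries lay between 14.7 and 21.7 CPM for Podxl and between 32.4 and 47.4 CPM for Hpd.

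Lists of genes fixed before the data were examined were tested with camera, which compares the genes of a list with all other genes. Of the 49 lists with enough members, 12 were higher and 9 lower in 5-Fu+BBR at an adjusted p under 0.05 with a preset correlation of 0.01 between genes. With an estimated correlation 0 of these calls held, the lowest adjusted p being 0.41, and fry, which does not compare a list with other genes, called 0 lists for change in a common direction. For change in either direction fry called 28 of the 49, among them interferon gamma and antigen presentation (adjusted p = 0.00369), smooth muscle (adjusted p = 0.00638) and T and NK cells (adjusted p = 0.0143), and also aryl hydrocarbon receptor targets (adjusted p = 0.000938) and goblet cells (adjusted p = 0.0023), which camera did not call. Fry for either direction also called sex-linked genes (adjusted p = 0.0023), heat shock genes (adjusted p = 0.0023) and skeletal muscle (adjusted p = 0.0373). It needs only some members to differ, and 3128 of the 20101 genes had an unadjusted p under 0.05. Such a call is therefore not particular to what a list stands for. Medians per library did not overlap between the groups for 7 of the 12 higher and 1 of the 9 lower lists. At a preset correlation the test calls lists more readily, so each count below is given with its adjusted p from the estimated correlation.

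Genes of antigen presentation and interferon gamma response rose as a list (median log2 fold change 0.91, adjusted p = 6.86e-19 with camera; adjusted p = 0.41 with an estimated correlation). Of the 30 members tested, 2 passed over all genes tested and 13, all higher, when adjusted over the list alone. H2-Eb1 and H2-Aa, the next 2 members by p, were at 55.9 ± 10.8 against 176 ± 45.9 CPM and 58.6 ± 16.2 against 183 ± 40.1 CPM (log2 fold changes 1.66 ± 0.23 and 1.64 ± 0.24, adjusted p = 0.0705 and 0.0717 over all genes). The members that passed over the list alone were class II genes and their regulator Ciita (log2 fold change 1.61), and genes of the class I pathway such as B2m (1.18), Tap2 (0.89) and the regulator Nlrc5 (1.47). The list medians relative to the 5-Fu mean were 0.29, 0.02, -0.28 in the 5-Fu libraries 1 to 3 and 1.26, 1.33, 0.06 in the 5-Fu+BBR libraries 1 to 3, so 5-Fu+BBR replicate 3 lay within the range of 5-Fu. Genes of the type I interferon response were also higher as a list (median 1.45, adjusted p = 3.7e-12; adjusted p = 0.563 with an estimated correlation). All 29 members had positive log2 fold changes, but 0 passed, over all genes or adjusted over the list alone, and the groups overlapped for each of the 29. Its medians were -0.94, 0.83, 0.12 in the 5-Fu libraries and 2.08, 1.83, 0.27 in the 5-Fu+BBR libraries, in the same order, and 5-Fu+BBR replicate 3 again lay within the range of 5-Fu. Bst2, a restriction factor of enveloped viruses, was at 56.4 ± 21.9 against 175 ± 91.3 CPM (adjusted p = 0.251).

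Markers of lymphocytes and dendritic cells were higher in 5-Fu+BBR. All 25 T and NK cell genes had positive log2 fold changes (median 1.20, adjusted p = 4.36e-13; adjusted p = 0.41 with an estimated correlation). Of them 0 passed over all genes, and 14, all higher, passed when adjusted over the list alone. Lck, a kinase of T cell receptor signalling, was at 8.82 ± 1.28 against 21.5 ± 4.59 CPM and Cd247, the zeta chain of that receptor, at 1.81 ± 0.757 against 6.67 ± 1.54 CPM (log2 fold changes 1.28 ± 0.20 and 1.87 ± 0.35, adjusted p = 0.0752 and 0.098 over all genes). The B and plasma cell list had a median of 1.49 over 21 genes (adjusted p = 1.33e-14; adjusted p = 0.444 with an estimated correlation). Of its members 7, all higher, passed when adjusted over the list alone against 0 over all genes. The immunoglobulin kappa constant gene Igkc was at 709 ± 259 against 1987 ± 640.3 CPM and the IgA heavy chain gene Igha at 873 ± 298 against 2429.9 ± 969.7 CPM (log2 fold changes 1.49 ± 0.33 and 1.48 ± 0.37). Of the 11 dendritic cell genes, 7 passed when adjusted over the list alone and 0 over all genes (median 1.58, adjusted p = 1.59e-10; adjusted p = 0.41 with an estimated correlation). Clec9a of cross-presenting dendritic cells was at 0.362 ± 0.108 against 2.3 ± 0.805 CPM and Cd83 at 8.88 ± 3.41 against 26.5 ± 3.45 CPM. Among macrophage and monocyte genes 15 had positive and 3 negative log2 fold changes. Csf1r (0.70 ± 0.10), Lyz2 (0.76 ± 0.17) and Ms4a7 (0.85 ± 0.19) were higher and the scavenger receptor Cd163 (-1.01 ± 0.29) lower when adjusted over the list alone. Of the 18 members 0 passed over all genes (median 0.32, adjusted p = 0.0135; adjusted p = 0.566 with an estimated correlation).

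**Figure D3:**
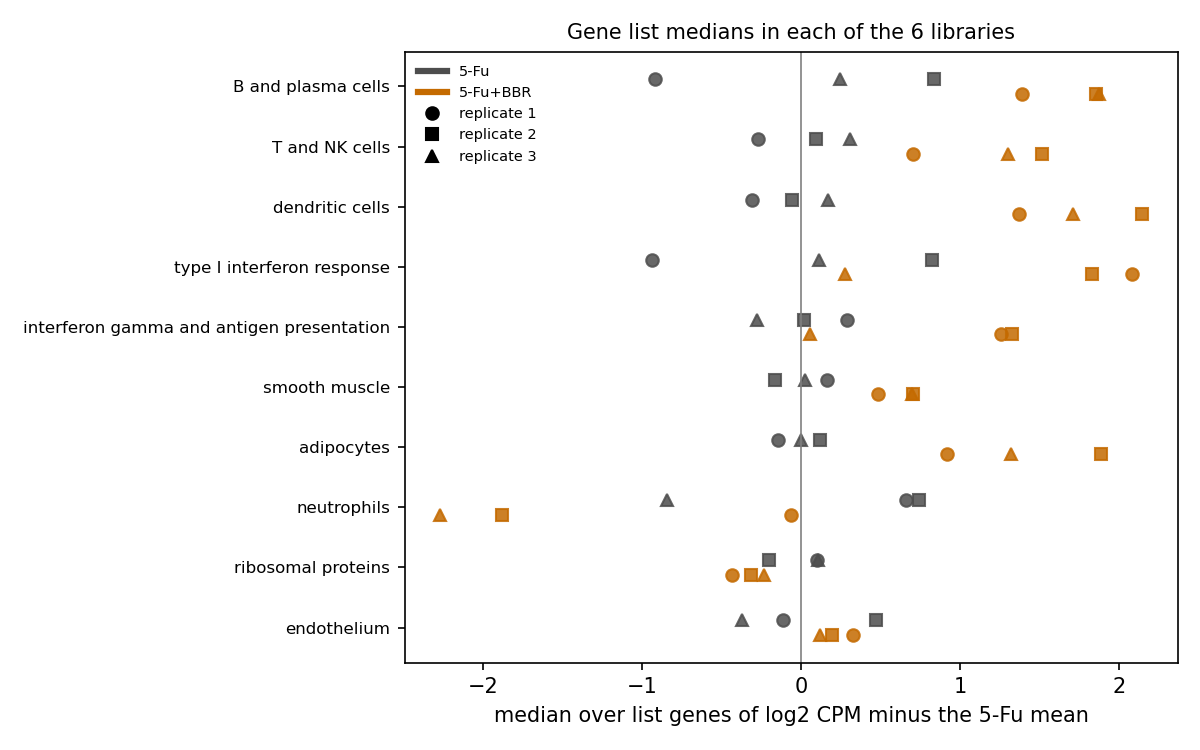
Median over the genes of 10 lists of log2 CPM minus the 5-Fu mean of each gene (horizontal axis), with 1 point per library, coloured by group and shaped by replicate number. The 3 libraries of 5-Fu+BBR lay above those of 5-Fu for B and plasma cells, T and NK cells, dendritic cells, smooth muscle and adipocytes, whereas 5-Fu+BBR replicate 3 lay within the range of 5-Fu for the type I interferon response (0.27) and for interferon gamma and antigen presentation (0.06). For neutrophils 5-Fu replicate 3 (-0.85) lay below 5-Fu+BBR replicate 1 (-0.06).

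Smooth muscle and fat markers also separated the groups. All 16 smooth muscle genes had positive log2 fold changes (median 0.63, adjusted p = 3.11e-12; adjusted p = 0.41 with an estimated correlation). Of them 10 passed when adjusted over the list alone against 0 over all genes. Actg2, the enteric actin of smooth muscle, was at 379.6 ± 97.1 against 837 ± 64.6 CPM and calponin Cnn1 at 215 ± 37 against 399.9 ± 25 CPM (log2 fold changes 1.14 ± 0.20 and 0.90 ± 0.15). Adipocyte genes had a median of 1.36 over 15 genes (adjusted p = 3.7e-12; adjusted p = 0.41 with an estimated correlation). When adjusted over the list alone 11 were higher, against 0 over all genes. Cidec, a lipid droplet protein, was at 1.78 ± 0.753 against 9.43 ± 1.6 CPM, and the fatty acid binding protein Fabp4 at 20.9 ± 5.14 against 53.5 ± 19.4 CPM. Leptin (Lep) had 0 counts in the 3 libraries of 5-Fu and was at least 14.4-fold higher in 5-Fu+BBR, measured against a floor of 12 counts over the group. Mast cell and eosinophil genes (median 1.62 over 11 genes, adjusted p = 0.00235; adjusted p = 0.563 with an estimated correlation) had 3 members higher over the list alone and 0 over all genes. The mast cell protease Mcpt1 was at 1.44 ± 0.677 against 10.1 ± 10.3 CPM. The medians of the mast cell and eosinophil list were 0.38, 2.74 and 1.07 in 5-Fu+BBR 1 to 3, highest by far in replicate 2. Red blood cell and platelet genes were higher as a list (median 1.21 over 10 genes, adjusted p = 0.0159; adjusted p = 0.566 with an estimated correlation). Of its members 0 passed over all genes or over the list alone, and Hbb-bs was at 3.98 ± 3.27 against 30.1 ± 24.9 CPM. Tuft cell genes (median 0.61 over 13 genes, adjusted p = 0.0135; adjusted p = 0.563 with an estimated correlation) had 0 members past either threshold. Dclk1 was at 8.18 ± 3.22 against 13.3 ± 3.31 CPM. Immediate early genes (median 0.40 over 15 genes, adjusted p = 0.0135; adjusted p = 0.563 with an estimated correlation) had 4 members higher over the list alone and 0 over all genes. Fos was at 81.5 ± 9.82 against 153 ± 30.2 CPM.

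Among 17 circadian clock genes, 2 passed over all genes, and 7 were higher and 4 lower when adjusted over the list alone. Besides Dbp and Nr1d1, Nr1d2 (log2 fold change 0.54 ± 0.13), Bhlhe41 (1.59 ± 0.42), Hlf (1.05 ± 0.33), Tef (0.40 ± 0.13) and Ciart (0.94 ± 0.30) were higher over the list alone. Cry1 (-0.77 ± 0.17), Nfil3 (-1.13 ± 0.30), Clock (-0.43 ± 0.12) and Arntl (-0.63 ± 0.19), which encodes the clock activator BMAL1, were lower over the list alone. As a list they did not pass camera, which tests a common direction (median 0.04, adjusted p = 0.0828). They were among the 28 of 49 lists that passed fry for change in either direction (adjusted p = 0.00296), members going both ways.

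The lists that were lower in 5-Fu+BBR changed by small amounts, except for neutrophil genes. Ribosomal protein genes had a median of -0.36 with 24 of 24 negative (adjusted p = 2.23e-08; adjusted p = 0.563 with an estimated correlation). Cholesterol synthesis genes had a median of -0.45 with 21 of 21 negative (adjusted p = 2.24e-06; adjusted p = 0.566 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of -0.21 with 28 of 28 negative (adjusted p = 0.000123; adjusted p = 0.703 with an estimated correlation). Per library the groups did not overlap in the median of ribosomal protein genes, the only one of the 9 lower lists of which this held. They overlapped for oxidative phosphorylation (0.10, -0.26, 0.18 in 5-Fu 1 to 3 and -0.36, -0.17, -0.10 in 5-Fu+BBR 1 to 3) and cholesterol synthesis (0.20, 0.06, -0.22 and -0.10, -0.33, -0.79). Of the members of the 3 lists, 0 passed over all genes or adjusted over the list alone. Rps6 was at 903 ± 97.5 against 685 ± 18.4 CPM, Hmgcs1 of the mevalonate pathway at 559.6 ± 72 against 382 ± 87.4 CPM and Ndufa4 at 159.7 ± 16.8 against 125 ± 7.3 CPM. NRF2 targets (median -0.23, adjusted p = 0.00148; adjusted p = 0.563 with an estimated correlation) had 4 of 18 members lower over the list alone and 0 over all genes. They were Gsta4 (135 ± 25.1 against 60.3 ± 14.9 CPM), Gsta1, Txnrd1 and Gsr, enzymes of glutathione and thioredoxin metabolism. Tight and adherens junction genes (median -0.13, adjusted p = 0.00671; adjusted p = 0.672 with an estimated correlation) had 2 of 23 lower over the list alone and 0 over all genes. These were Cgnl1 (69.4 ± 10.9 against 43.2 ± 3.81 CPM) and the claudin Cldn8 (181 ± 38.8 against 91.1 ± 17.1 CPM). The p53 target list (median -0.19, adjusted p = 0.0198; adjusted p = 0.563 with an estimated correlation) had 0 members past either threshold. So did the cell cycle list (median -0.19, adjusted p = 0.0195; adjusted p = 0.843 with an estimated correlation). Tnfrsf10b was at 16.2 ± 1.61 against 10.8 ± 1.39 CPM, Bax at 41.5 ± 7.59 against 31.8 ± 0.898 CPM and Rrm2 at 41.2 ± 9.62 against 31.1 ± 2.31 CPM.

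Neutrophil genes had a median of -1.31 over 15 genes (adjusted p = 0.000294; adjusted p = 0.563 with an estimated correlation), with 1 member lower over the list alone and 0 over all genes. That member, the antimicrobial peptide gene Camp, had 0 counts in the 3 libraries of 5-Fu+BBR and was at least 10.3-fold lower there, against the floor of 12 counts over the group. The medians per library were 0.66, 0.74, -0.85 in 5-Fu 1 to 3 and -0.06, -1.88, -2.27 in 5-Fu+BBR 1 to 3. The groups overlapped, and the lowest values were those of 5-Fu+BBR replicates 2 and 3, the libraries with the highest kidney transcripts. With Camp at its bound the median was the same, -1.31. The collagenase gene Mmp8 was at 1.72 ± 1.37 against 0.101 ± 0.176 CPM, and Cd177 went the other way (431 ± 146 against 687 ± 195 CPM). Antimicrobial defence genes (median -0.23 over 24 genes, adjusted p = 0.0159, and 0.566 with an estimated correlation) had 0 members past either threshold. Their medians per library were 0.041, -0.083 and -0.003 in 5-Fu 1 to 3 and 0.137, -0.368 and -1.009 in 5-Fu+BBR 1 to 3. The fall thus rested on 5-Fu+BBR replicates 2 and 3, while replicate 1 lay above every 5-Fu library. The acute phase gene Saa3 was at 58.8 ± 22.3 against 5.76 ± 5.22 CPM (log2 fold change -3.35 ± 0.72, adjusted p = 0.151), and Reg4 at 319.5 ± 66.2 against 563 ± 217 CPM (log2 fold change 0.82 ± 0.28, adjusted p = 0.241).

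**Figure D4:**
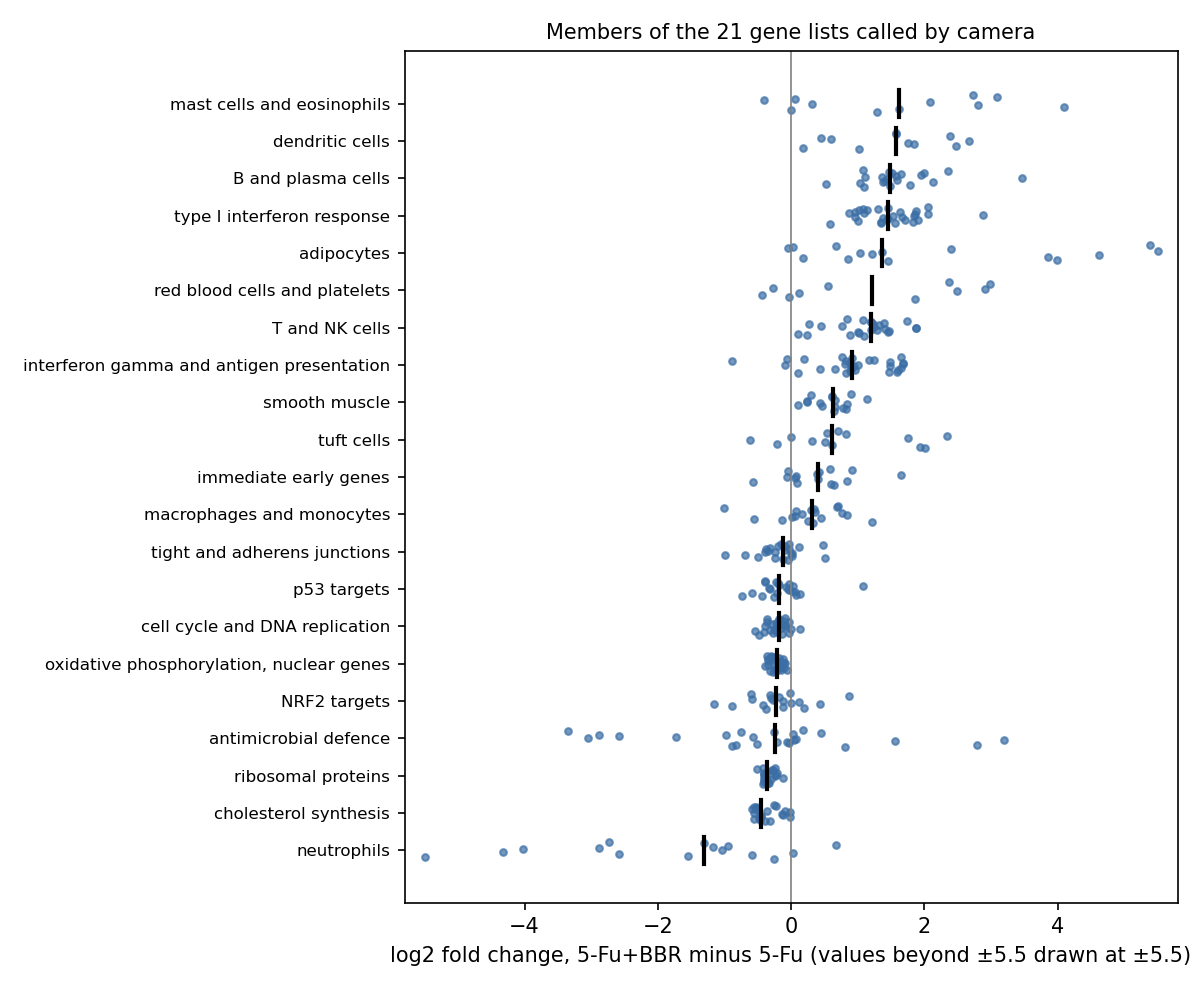
Log2 fold change, 5-Fu+BBR minus 5-Fu, of each member (points) of the 21 lists called by camera with a preset correlation, with a black bar at the list's median; values beyond the axis limits are drawn at its ends. Medians ran from -1.31 for neutrophils to 1.62 for mast cells and eosinophils.

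Of the 22 key genes of mucosal damage and barrier function chosen before the data were examined, 20 were tested, and 0 passed over all genes or adjusted over the list alone. The stem cell marker Lgr5 was at 4.61 ± 1.55 against 6.04 ± 2.29 CPM, the proliferation marker Mki67 at 163 ± 51.9 against 163 ± 25.2 CPM, and the p53 target Cdkn1a at 278 ± 32.8 against 270.4 ± 34.6 CPM. The mucin gene Muc2 was at 2299 ± 429.8 against 3025 ± 945 CPM, the tight junction genes Tjp1 and Ocln at 173 ± 18.1 against 146 ± 21.6 CPM and 119 ± 10.3 against 95.6 ± 14.8 CPM, and the claudins Cldn1 and Cldn2 at 3.82 ± 0.235 against 2.92 ± 0.693 CPM and 102 ± 24.4 against 103 ± 6.91 CPM. Dpyd, which encodes the enzyme that degrades 5-fluorouracil, was at 3.62 ± 1.3 against 8.14 ± 2.67 CPM (log2 fold change 1.17 ± 0.34, adjusted p = 0.186). Tyms, the target of the drug, was at 31.6 ± 7.24 against 25.5 ± 1.66 CPM (log2 fold change -0.31 ± 0.17, adjusted p = 0.436). The inflammatory cytokine genes Il1b and Tnf were at 6.66 ± 2.84 against 5.82 ± 0.941 CPM and 9.22 ± 1.2 against 9.68 ± 6.03 CPM, and the antimicrobial protein gene Lcn2 was at 14.5 ± 6.72 against 1.74 ± 1.71 CPM (log2 fold change -3.05 ± 0.88, adjusted p = 0.211). Reg3b, Reg3g, Lypd8, Pigr, Aqp8, Car1 and Slc26a3 had log2 fold changes of -0.76 ± 1.35, -0.57 ± 1.41, 0.05 ± 0.22, 0.18 ± 0.21, 1.55 ± 0.87, -0.33 ± 0.53 and -0.09 ± 0.54. The direction of Mki67, Cdkn1a, Cldn2, Il1b, Tnf, Reg3b, Reg3g, Lypd8, Car1 and Slc26a3 changed under at least 1 alternative or without 1 library. Il6 and Cyp1a1 were too low to be tested.

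The remaining lists did not pass camera. Epithelial lists had medians of 0.14 for crypt stem cells, 0.22 for goblet cells, 0.05 for absorptive colonocytes and 0.08 for enteroendocrine cells. Over the list alone Prom1 was lower among stem cell genes and Muc4 (log2 fold change 1.04) higher among goblet cell genes. Genes of fluorouracil and pyrimidine metabolism had a median of -0.09 and a mean of 0.13, of opposite sign. Over the list alone Upp1 (1.08), Upb1 (1.39) and Dpyd were higher and Ppat (-0.71) lower. Cell death genes had a median of -0.07, and Ripk3 (-0.83), Apaf1 (-0.64) and Bcl2l1 (-0.44) were lower over the list alone. The median was -0.16 for inflammatory cytokines and 0.04 for pattern recognition, of which Tlr9 (2.03), Tlr7 (1.36) and Tlr1 (0.40) were higher over the list alone. Endothelium, enteric neurons and glia, and fibroblasts and matrix had medians of 0.15, 0.18 and 0.32, with 0 members past either threshold. Among aryl hydrocarbon receptor targets (median 0.20), Ahrr (1.66) and Aldh3a1 (1.3) were higher over the list alone. Metabolic lists had medians of 0.31 for xenobiotic metabolism, 0.03 for bile acid signalling, -0.05 for fatty acid oxidation, 0.14 for fatty acid synthesis and 0.04 for mitochondrially encoded genes. In them Nr1h4 (-0.54) was lower and Thrsp (3.46) higher over the list alone. Medians were -0.05 for the unfolded protein response, -0.11 for heat shock genes, 0.32 for the Wnt pathway, 0.10 for the Notch pathway and 0.24 for histones. Hspb1 and Cryab of the heat shock genes were higher over the list alone. Lists of other tissues and positions had medians of -0.19 for skeletal muscle, -0.14 for squamous epithelium, 0.16 for small intestine, 0.15 for distal colon position and 0.04 for sex-linked genes. Over the list alone Lyz1, Anpep and Fabp2 of the small intestine and Hoxa9 and Hoxa10 of colon position were higher, and the Y-linked Uty (-0.43) lower. Exocrine pancreas had 3 genes tested and no list test. The test and the median differed in sign for bile acid signalling, mitochondrially encoded genes and sex-linked genes. The mean and the median differed in sign for enteroendocrine cells (-0.02), skeletal muscle (0.10) and bile acid signalling (-0.17).

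The count of genes that passed depended on single libraries. The 15 genes kept the direction of their log2 fold changes with each library left out and with 5-Fu+BBR replicate 1 alone. Since the groups did not overlap for these genes, leaving out libraries could hardly reverse them, so the kept direction is no separate support. Without 5-Fu replicate 1, and likewise without 5-Fu+BBR replicate 2, edgeR called 0 genes, with 2062 and 1888 genes at an unadjusted p under 0.05. The log2 fold changes in these 2 settings were 1.67 and 1.64 for Cd74 (1.68 with all libraries), 1.56 and 1.61 for H2-Ab1 (1.68), 2.80 and 2.58 for C1qtnf3 (2.73) and -1.29 and -1.42 for Sgk1 (-1.46). DESeq2 then called 473 higher and 116 lower, and 255 higher and 105 lower, and limma-voom 0 in both cases. With 5-Fu+BBR replicate 1 alone against 5-Fu, 1 sample is left in that group and the spread comes from 5-Fu alone, so only log2 fold changes are given. In that setting, without the libraries with kidney transcripts, log2 fold changes were 1.46 for Cd74, 1.42 for H2-Ab1, 1.35 for H2-Q7, 2.76 for C1qtnf3, 1.17 for Dbp, -1.45 for Sgk1 and -1.11 for E2f2, against the same 5-Fu libraries as in the test of all 6. By edgeR the counts were 145 higher and 14 lower without 5-Fu replicate 2, 44 and 9 without 5-Fu replicate 3, 39 and 15 without 5-Fu+BBR replicate 1, and 16 and 1 without 5-Fu+BBR replicate 3. DESeq2 on all 6 libraries called 879 higher and 347 lower.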

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

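The alternatives chosen after the result was seen were counts divided by 4, edgeR's newer quasi-likelihood method, limma-trend on log2(FPKM + 1) and 5-Fu+BBR replicate 1 alone against 5-Fu. The 15 genes called kept their direction in every setting run. Their groups did not overlap, so leaving out libraries could hardly have changed this. The log2 fold changes of 10 of 122 named gene results and the medians of 17 of 49 lists changed sign in at least 1 setting; except for antimicrobial defence, none of these passed in the main test. What counts as a change of sign for a list was redefined after values were seen, and now covers a median of opposite sign or a call in the opposite direction. The cause was not tested unless stated.

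The replicate numbers gave no clear pairing of the libraries. Same-numbered libraries had weak positive correlations of 0.06, 0.02 and 0.12 in their deviations from the group means. Not every library correlated best with its own number, so whether the numbers mark pairs cannot be told. With the replicate block 91 genes were higher and 22 lower, and Tnf was at -0.09.

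Counts of genes higher and lower were 64 and 13 without a filter, 128 and 37 by limma-voom with sample weights, 879 and 347 by DESeq2 and 119 and 25 at an adjusted p under 0.1, and 5 were lower with counts divided by 4. Genes at least 2-fold lower at an unadjusted p under 0.05 numbered 283 without a filter and with sample weights, and 114 with at least 50 counts, where fewer genes were tested. On log2(FPKM + 1), which understates low genes, 277 were at least 2-fold higher and 43 lower, and 5 lists were lower. Camera with an estimated correlation and fry for a common direction called 0 lists higher and 0 lower, whereas fry for either direction called 28. With 5-Fu+BBR replicate 1 alone, a lone sample assumed to vary like 5-Fu, edgeR called 0 higher and 0 lower, with 1331 at an unadjusted p under 0.05 (other tools were not run), 469 at least 2-fold higher, and 3 lists lower. The log2 fold changes of genes called in the main test were then 1.46 for Cd74, 2.76 for C1qtnf3, 1.17 for Dbp and -1.45 for Sgk1.

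With that replicate alone, log2 fold changes were 0.12 for Cdkn1a, -0.10 for Cldn2, 0.72 for Reg3b and 0.90 for Reg3g, and list medians were 0.01 for apoptosis, 0.02 for antimicrobial defence, -0.02 for enteric neurons and glia, -0.06 for small intestine, -0.18 for sex-linked genes, -0.20 for bile acid signalling, 0.05 for the unfolded protein response and -0.23 for histones. Mki67 was at -0.01 without a filter, with DESeq2 size factors and by DESeq2, and at -0.10 with sample weights, which also gave -0.05 for Cldn2, -0.28 for Tnf, -0.02 for Lypd8 and -0.01 for the Notch pathway. Tnf was at -0.09 by limma-voom and -0.06 on log2(FPKM + 1), where pattern recognition was at -0.03 and sex-linked genes at -0.10. Small intestine was at -0.42 without a filter and skeletal muscle at 0.33 with counts divided by 4.

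Leaving out each library in turn gave between 0 and 145 genes higher, 0 and 15 lower, and 144 and 295 at least 2-fold lower at an unadjusted p under 0.05. The counts of 0 came without 5-Fu replicate 1 and without 5-Fu+BBR replicate 2, with 2062 and 1888 genes at an unadjusted p under 0.05 by edgeR, 473 higher and 116 lower and 255 higher and 105 lower by DESeq2, and 0 by limma-voom. In these 2 settings log2 fold changes were 1.67 and 1.64 for Cd74, 0.94 and 0.86 for Cav1 and -1.29 and -1.42 for Sgk1, against 1.68, 0.91 and -1.46 with all libraries. The log2 fold change of Reg3g lay between -3.87 and 0.21. Lowest and highest log2 fold changes were -0.13 and 0.05 for Cdkn1a, -0.49 and 0.09 for Il1b, -0.16 and 0.17 for Lypd8, -0.23 and 0.17 for Mki67, -0.14 and 0.20 for Cldn2, -0.56 and 0.37 for Tnf, -0.70 and 0.33 for Car1, and -0.59 and 0.37 for Slc26a3. Lowest and highest medians were -0.15 and 0.07 for skeletal muscle, -0.09 and 0.19 for mitochondrially encoded genes, -0.08 and 0.35 for absorptive colonocytes, -0.09 and 0.29 for enteroendocrine cells, -0.58 and 0.05 for squamous epithelium, -0.08 and 0.20 for small intestine, -0.14 and 0.06 for the unfolded protein response, -0.14 and 0.02 for apoptosis, -0.03 and 0.46 for distal colon position, -0.16 and 0.02 for fatty acid oxidation, -0.09 and 0.09 for pattern recognition, -0.04 and 0.13 for sex-linked genes, -0.03 and 0.24 for bile acid signalling and 0.00 and 0.17 for the Notch pathway.

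Not run were the other pseudocounts, quantile normalization and limma without trend, which were meant for a table without counts. Low genes are limited by depth, since 1 fragment can be worth about 4 counts.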

Other observations

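The KEGG pathways, the receptor segments, the acute phase list and the tests of the splits, of the share of the main cell type, of the interferon response and of the clock genes were chosen after the result was seen.

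Outside the lists, 307 KEGG pathways were tested with camera, and 33 were higher and 20 lower in 5-Fu+BBR with a preset correlation, against 0 with an estimated correlation (lowest adjusted p = 0.435). Antigen processing and presentation had a median log2 fold change of 0.81 over 72 genes (adjusted p = 1.8e-21; adjusted p = 0.459 with an estimated correlation), and the intestinal network for IgA production 0.95 over 39 genes (adjusted p = 3.45e-20; adjusted p = 0.459 with an estimated correlation). Terpenoid backbone biosynthesis, which feeds cholesterol synthesis, had a median of -0.27 over 21 genes (adjusted p = 1.91e-05; adjusted p = 0.459 with an estimated correlation). Of 178 immunoglobulin segments tested, 167 had positive log2 fold changes, 82 were higher and 0 lower by edgeR at an unadjusted p under 0.05, and of 21 T cell receptor segments 20 were positive, 6 higher and 0 lower. Of 20 acute phase genes, the 10 whose values had been seen when they were chosen, Saa3 and Lcn2 among them, all had negative log2 fold changes (median -1.62), and the other 10 had a median of -0.71 with 7 negative, 2 at an unadjusted p under 0.05. Medians of the 20 per library were -0.37, 0.08 and 0.24 in 5-Fu 1 to 3 and -0.60, -1.10 and -1.40 in 5-Fu+BBR 1 to 3, lowest in the 2 libraries with the highest kidney transcripts.

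The real grouping gave 15 genes at an adjusted p under 0.05, against at most 1 in the other splits of the 6 samples into 3 and 3, and 1 of the 10 splits, the real one, gave as many. For genes changed at least 2-fold at an unadjusted p under 0.05 the real grouping gave 1131 against at most 600, and again 1 of 10 splits gave as many. For gene lists it gave 21 against at most 22, and 2 of 10 splits gave as many. For lists changed in either direction by fry it gave 28 against at most 1, and 1 of 10 splits gave as many. With 10 splits no share under 0.05 can be reached.

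Kidney transcripts were higher in 5-Fu+BBR replicates 2 and 3. Kidney genes written down before their values were seen had a median log2 fold change of 2.25 over 22 genes, which is consistent with kidney RNA in those libraries. Induction of kidney genes in colon cells by berberine stays open: 3 of 4 nephron segments had a gene at least 2-fold higher at an unadjusted p under 0.05, and the podocyte genes tested, Nphs1 and Podxl, were also present in the 5-Fu libraries at 14.7 CPM or more, a level that would hide a small share. Relative to the 5-Fu mean, the log2 median of the kidney genes written down beforehand was 0.15 in 5-Fu+BBR replicate 1. It was 2.52 and 2.74 in replicates 2 and 3. Induction in every sample given berberine was thus not seen, although this rests on 1 library. Whether kidney RNA may have entered at dissection or at library preparation was not tested.

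Lymphocyte and antigen presentation genes were higher in 5-Fu+BBR. A lower share of the main cell type would raise markers of the other cell types alike. Lymphocyte markers exceeded endothelium, neuron, glia and fibroblast markers by 1.14 in median log2 fold change, compared after the list medians had been seen. The two-sided permutation p over genes was 1e-05, the smallest that the permutations can give. Genes are not independent replicates, so this p measures no spread between samples and decides nothing. The unlike medians themselves argue against a lower share as the whole cause. Medians of further types lay apart as well, at 0.63 for smooth muscle, 1.36 for adipocytes, 1.62 for mast cells and eosinophils and -1.31 for neutrophils, so some types rose as lymphocyte markers did. Lymphocyte genes written down before their values were seen had a median of 1.21, with 24 of 25 positive. More lymphocytes or lymphoid tissue in the pieces, whether from berberine or from sampling, may account for this rise. The 1 negative gene was the chemokine gene Cxcl13 (log2 fold change -0.18 ± 0.11, adjusted p = 0.491 by edgeR). For an interferon response in all 5-Fu+BBR samples, 2 of the 3 libraries had a type I interferon median above every 5-Fu library. 5-Fu+BBR replicate 3 (0.27) lay below 5-Fu replicate 2 (0.83), which met the condition written against such a response in all samples. A response above every 5-Fu library was thus not seen in all 3. Whether 5-Fu+BBR replicate 3 had a weaker response cannot be told from 1 library.

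Clock genes and the corticosteroid target Sgk1 differed between the groups. A shift in clock phase or time of collection may account for the clock genes: 13 of 13 moved as 2 opposite phases, but these genes were chosen after their values were seen and collection time cannot be told apart from group. Lower corticosteroid signalling was raised by 8 targets whose values had been seen, all negative (median log2 fold change -1.44, 7 of them at an unadjusted p under 0.05), and was tested on 19 targets written down before their values were seen, with a median of -0.04 (interquartile range -0.38 to 0.10). This met the bound of above -0.1 set beforehand against that explanation, and 9 targets were positive and 10 negative. It argues against a shared fall of these 19 targets. The 8 targets whose values had been seen, Sgk1 among them, are not covered by it. The readings given here of the clock shift and the interferon response were chosen after these values were seen. So was the limit of the corticosteroid reading to these 19 targets.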
